A study of Drosophila melanogaster with 2 samples.

How the data were processed

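The data are peak lists from ChIP-seq with an antibody against GFP on whole adult flies of both sexes that express a Capicua-GFP fusion. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels describe both libraries as biological replicates, numbered 1 and 3, of 1 group. They do not say how the flies of each were raised, so the spread between them may be partly technical.

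The authors deposited, per the text list that goes with the files, a relaxed peak list for each replicate, a relaxed list for both pooled and a list of peaks past a threshold on the irreproducible discovery rate (IDR), each on the dm6 and dm3 genome builds. Each was made from the replicates' alignments with a control alignment, per the same list. The aligner, the peak caller and their settings are not given in the sources used here. The score of a peak is the authors' deposited peak strength, with no fixed range and no stated scaling for depth, and it was used here to rank and describe peaks. The deposited −log10 of the q-value reaches a ceiling of 4.51 on dm6 that 100% of the reproducible peaks share, so it was not used to rank them. The relaxed lists hold 30000 entries each. All 7152 entries of the reproducible dm6 list are the 7152 highest-scoring entries of the pooled list, and 441 of them repeat an interval with another summit. The word reproducible is therefore only the name of this list, whose peaks need not each agree between replicates. In it, 3 summits lie outside their interval and were used as given. The files used here hold no read counts, so depth is unknown, and p-values and intervals cover counting error only: they treat peaks or genes as independent, which neighbouring peaks are not.

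Coordinates are dm6 as the files give them, converted to 1-based positions. Sequence came from the RefSeq Release 6 assembly of D. melanogaster, which is dm6, and genes from Ensembl release 115, on the 6 major arms. No dm3 coordinates were converted, and a dm3 genome was not used here. A promoter peak is a summit within 1000 bp of any transcript start of a protein-coding gene. A summit counts for every gene with a start within that distance, so it may lie nearer to the start of another gene. Summits were assigned to the first of promoter, 5' UTR, coding exon, 3' UTR, intron and intergenic. Random positions were drawn from non-N bases with the same number per arm, in 1000 sets. A peak was matched to the strongest replicate peak that overlaps it by 1 bp or more; neighbouring summits of an interval therefore often share a replicate score, and the mean ± SD of replicate scores is over these matches. Beside the observed matches, 20 sets of random intervals of the same widths were matched.

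Octamers were sought on both strands within 100 bp of each summit and in a window of the same width centred 1000 bp to a side drawn at random. The exact McNemar test compares them. All octamers were ranked by the z of summit against mean flank counts. Shares across peak strength were tested with 100000 permutations. Gene lists and non-coding classes were compared with Fisher's exact test, two-sided, and arms with an exact binomial test against non-N length, two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Odds ratios have 0.5 added to each cell. Intervals of shares are exact Clopper-Pearson at 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

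The groups, the tests, the 26 gene lists, the 10 motifs and most alternatives were fixed before the data were examined; alternatives added later are named where they are reported. Named genes follow a rule fixed at the same time: the protein-coding gene with the start nearest to each of the 25 strongest peaks, every measured member of the list of known Capicua targets and cic, and in each other list up to 4 members with the strongest promoter peak, with the count alone for lists that are bound less often. List members were matched by current symbol or synonym, with 4 ambiguous older symbols assigned by hand. The 25 names of the testis list stand for 22 genes, and mir-ban is not protein-coding and was kept out of the list test. Genes of ribosomal proteins, the respiratory chain, the proteasome, chemosensory receptors and histones were taken by a name pattern, which may admit genes that only share the name. The octamer copies at pnt were described after their values were seen.

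The procedures were tested on simulated data. Promoter positions planted in 50% of 7152 places gave a share of 60.4%, where 60.2% was expected from the planting. Octamers planted in 10% of windows gave an excess of 9.87 percentage points, and TGAATGAA then ranked 1. Both planted gene lists, and 0 of 24 unchanged lists, passed in a simulation over 13945 genes. Random positions gave a promoter p under 0.05 in 1 of 20 sets and an octamer p under 0.05 in 0 of 20. Peaks drawn by length gave an arm past the threshold in 1 of 20 sets.

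Alternatives were: the strongest 7152 relaxed peaks of either replicate alone, the stronger 50% of peaks, other windows of 50 and 200 bp and other promoter distances of 500, 2000 and 5000 bp, other backgrounds, other rules of overlap, the dm3 lists, 1 summit per merged region, and class shares outside promoters. The closing section gives their effect.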

Results

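Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole adult Drosophila melanogaster, males and females pooled, from a line that carries Capicua (cic) with GFP at its C-terminus. Capicua is an HMG-box repressor whose activity is relieved by receptor tyrosine kinase and ERK signalling. Chromatin bound by the fusion was recovered with an antibody against GFP. There was 1 group with 2 biological replicates, numbered 1 and 3 in the labels, so the series allows a comparison between replicates and of bound with unbound sequence, and none between conditions. The authors' list of peaks that passed their reproducibility threshold held 7152 entries on the dm6 genome, in 6120 separate regions, and a list of 30000 relaxed peaks stood behind each replicate. The values are the authors' peak scores. The files used here hold no read counts, so the depth of each library is unknown.

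The 25 strongest peaks included sites at genes of receptor tyrosine kinase signalling and at the gene for Capicua itself, below 4 stronger peaks near fzy, ETHR, MESR6 and CG11050; no enrichment of a gene group among the 25 was tested. Both sty, which encodes the receptor tyrosine kinase antagonist Sprouty, and cic held 2 of the 25 strongest peaks. At sty, an intronic peak on 3L from 3420126 to 3420755 scored 1887 (946 ± 224 in the replicates' own lists, SD, n = 2), and a promoter peak from 3417761 to 3419109 scored 1771 (891 ± 25.7, SD, n = 2). Mkp3, an ERK phosphatase, had a promoter peak of 1533 (768 ± 82.3, SD, n = 2), and spi, which encodes the EGFR ligand Spitz, had a promoter peak of 1406 (710 ± 6.59, SD, n = 2). An intronic peak 3471 bp from the nearest start of Socs36E, a suppressor of cytokine signalling, scored 1316 (661 ± 21.3, SD, n = 2).

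The strongest peak of all, on 2L from 16314705 to 16315536, scored 3067 (1535 ± 66.3, SD, n = 2). It lay in an intron of cact, the IκB homologue of the Toll pathway (named after its values were seen), and 4155 bp from the nearest protein-coding start, that of the cell-cycle gene fzy. The second, with a score of 2758, lay 182 bp from the start of ETHR, the receptor of ecdysis-triggering hormone. MESR6 followed with 2609 and CG11050 with 2237. Among metabolic genes, Pdk1, a kinase of insulin signalling, had a promoter peak of 1627, and Pepck2, a gluconeogenic enzyme, an intronic peak of 1531. Among regulators of chromatin and transcription, ash2, of the Trithorax group, scored 1592, spen scored 1588, shn, a zinc-finger protein of the BMP pathway, scored 1566, crp scored 1427 and Kr-h1, a juvenile hormone response factor, scored 1337. The other peaks of the 25 were nearest to jigr1 (1644), omd (1626), CG14657 (1480), Syp (1446), CG31678 (1383), bun (1376) and Pino (1330). Replicate scores were farthest apart, relative to their mean, at Syp (724 ± 260, SD, n = 2) and at shn (787 ± 278, SD, n = 2), and the higher replicate was replicate 1 at Syp and replicate 3 at shn.

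At cic, on 3R from 20252770 to 20303942, 16 summits fell in the gene or its promoters. The highest, from 20260983 to 20262863 in an intron, scored 2005 (1012 ± 74.4, SD, n = 2), and another intronic peak, from 20252404 to 20254437, scored 1362 (686 ± 21.5, SD, n = 2).

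The question of which sequence lies under the summits was addressed first with the octamers TGAATGAA and TGAATGGA, which are known binding sites of Capicua. Of the 25 strongest peaks, 9 had an octamer within 100 bp of the summit (36.0%, 95% exact interval 18.0 to 57.5), and so did 25 of the strongest 100. The sty intronic peak held both: TGAATGAA at 3L 3420507 to 3420514, in the sequence CTTTTTTATGAATGAAATGAACGG, and TGAATGGA at 3420536 to 3420543, in GATTATAATGAATGGAATTGGAGG. The octamer of the Mkp3 promoter lay on the minus strand of 3L at 19072468 to 19072475, 39 bp from the summit, in GGTACCTGTGAATGAATAGCTTGC. That of spi lay at 2L 19576571 to 19576578, 30 bp from the summit, in ATGAGCAATGAATGAAATTCGGTT, and that of Pdk1 at 3L 128592 to 128599, in AGGCGATGTGAATGAATTGTGGAA. The octamer at ETHR was the TGAATGGA form, at 3R 21246809 to 21246816 on the minus strand, 17 bp from the summit. MESR6, CG14657, Pino and the lower of the cic peaks each had a TGAATGAA.

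Over all 7152 peaks, 374 had an octamer within 100 bp of the summit (5.23%, 95% exact interval 4.72 to 5.77), against 201 (2.81%) in windows 1000 bp to the side. The octamer stood at the summit alone in 356 peaks and in the flank alone in 183 (exact McNemar test, two-sided, p = 7.86e-14). Its share depended on the strength of the peak. It was 9.92% (8.42 to 11.6) in the strongest 20% of peaks, 5.45% (4.34 to 6.76) in the next 20%, and 3.77%, 3.08% and 3.92% in the weaker peaks, from stronger to weaker. The flanks of the same groups, from strongest to weakest, held octamers in 3.00%, 3.08%, 2.73%, 3.57% and 1.68%, so the fourth group showed no excess at summits; the excess was not tested within groups. The correlation across peaks between score and presence of an octamer was low (Spearman's rho = 0.0930, permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give), and peaks are not independent replicates. Within the strongest 20%, octamers were densest within 25 bp of the summit, at 38.5 per 1000 peaks in a 50 bp bin.

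**Figure D1:**
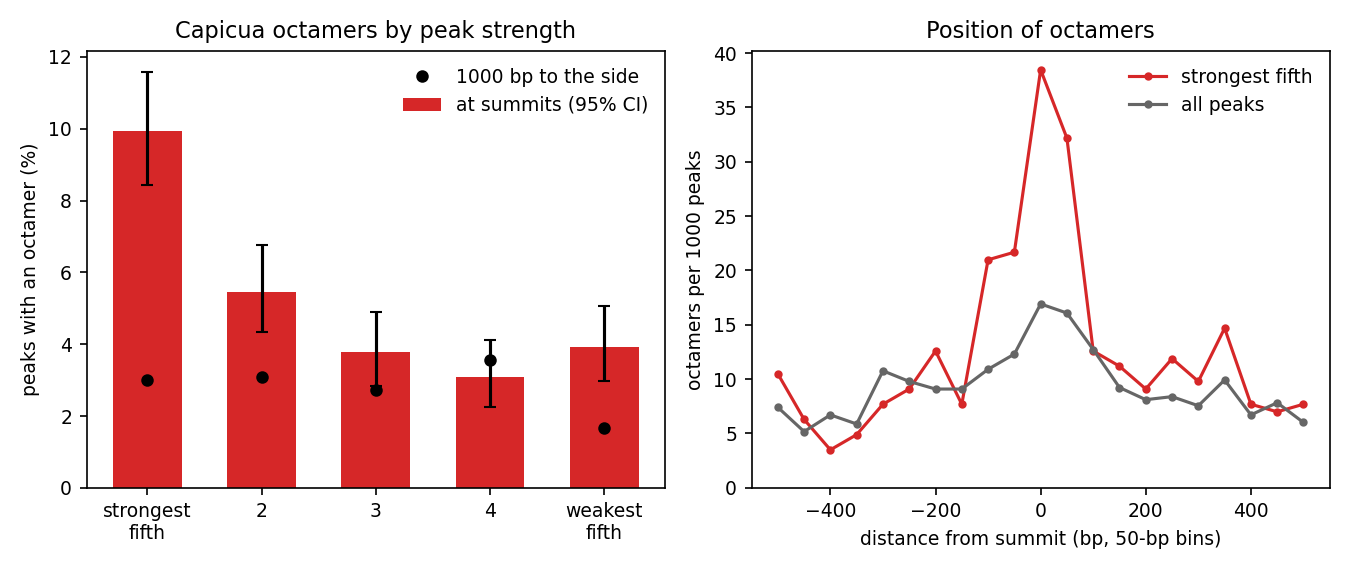
Left, percent of peaks with a Capicua octamer within 100 bp of the summit, from the strongest to the weakest 20% of peaks, with 95% exact intervals; black points give windows 1000 bp to the side. Right, octamers per 1000 peaks in 50 bp bins of distance from the summit; the share falls from 9.92% in the strongest peaks to 3.92% in the weakest, and the strongest peaks reach 38.5 per 1000 at the summit.

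Capicua octamers were not the sequences most enriched at summits. TGAATGAA ranked 51 among 32896 octamers (strands merged), with 277 summits against a mean of 130 per flank, and TGAATGGA ranked 2201, with 104 against 75. The first ranks went to CA repeats (CACACACA, 758 summits against 340.5), to GATA-type sequences (CTGATAAG, 342 against 104, and CTTATCGC, 283 against 75.5) and to the E-box-like AACAGCTG (343 against 125). In the strongest 20% of peaks TGAATGAA ranked 4, with 114 summits against 31. Without replicate 1 TGAATGAA ranked 68 and TGAATGGA 1307, and without replicate 3 they ranked 23 and 1359. All of these alternatives were chosen after seeing the data.

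Among the motifs fixed in advance, TGAATGAA was at 3.87% of summits and 1.83% of flanks (exact McNemar test, two-sided, adjusted p = 2.34e-13), and TGAATGGA at 1.45% and 1.05% (exact test, adjusted p = 0.0451). The call of TGAATGGA was lost among the stronger 50% of peaks and with 1 summit per merged region (exact test, adjusted p = 0.164 and 0.241). Its adjusted p was 0.00872 to 0.241 over the alternatives. Of 8 other motifs, 5 were more frequent at summits than in flanks, by exact McNemar tests with Benjamini-Hochberg adjustment over all 10 motifs. The GAGA element, bound by the Trl protein, was at 9.27% of summits and 4.03% of flanks (exact test, adjusted p = 2.90e-36), and Motif 1, a core promoter element, at 1.93% and 0.405% (exact test, adjusted p = 9.49e-18). The DRE, bound by Dref at promoters of broadly active genes, was at 2.71% and 0.881% (exact test, adjusted p = 3.54e-16). The excess of both lay at promoter summits, with the DRE at 3.91% against 1.10% in their flanks and Motif 1 at 2.94% against 0.497%. At other summits the DRE was at 0.515% against 0.475%, and Motif 1 at 0.0792% against 0.238%. TGAATGAA was above its flanks at promoter summits (3.57% against 1.41%) and at other summits (4.43% against 2.61%). These splits were not tested. The GATA site was at 2.60% and 1.12% (exact test, adjusted p = 6.67e-11) and the E-box CACGTG at 4.10% and 2.82% (exact test, adjusted p = 6.70e-05). The Zelda site was less frequent at summits, 0.909% against 1.43% (exact test, adjusted p = 0.00665). Neither AP-1 sites (2.64% against 2.21%, exact test, adjusted p = 0.109) nor ETS sites (0.182% against 0.252%, exact test, adjusted p = 0.473) passed. DRE and Motif 1 went with weak peaks: the DRE was at 1.33% of the strongest 20% and 4.13% of the weakest 20% (Fisher's exact test, adjusted p = 1.61e-05), and Motif 1 at 0.490% and 2.38% (Fisher's exact test, adjusted p = 5.58e-05). The GAGA element went the other way, from 12.1% in the strongest to 6.71% in the weakest (Fisher's exact test, adjusted p = 4.86e-06). Without replicate 1 the E-box lost its call (exact test, adjusted p = 0.0638, with 2.86e-06 to 0.0638 over the alternatives). In the same setting the ETS site passed as less frequent at summits (exact test, adjusted p = 0.00181, with 0.00181 to 0.581). The Zelda site lost its call without replicate 1, among the stronger 50% of peaks and with 1 summit per merged region (exact test, adjusted p = 0.112, 0.164 and 0.100). It kept its call only without replicate 3 (exact test, adjusted p = 0.0190). Among the stronger 50% of peaks the AP-1 site passed (exact test, adjusted p = 0.0442, with 0.0442 to 0.233 over the alternatives). All alternatives for motifs were chosen after seeing the data.

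**Figure D2:**
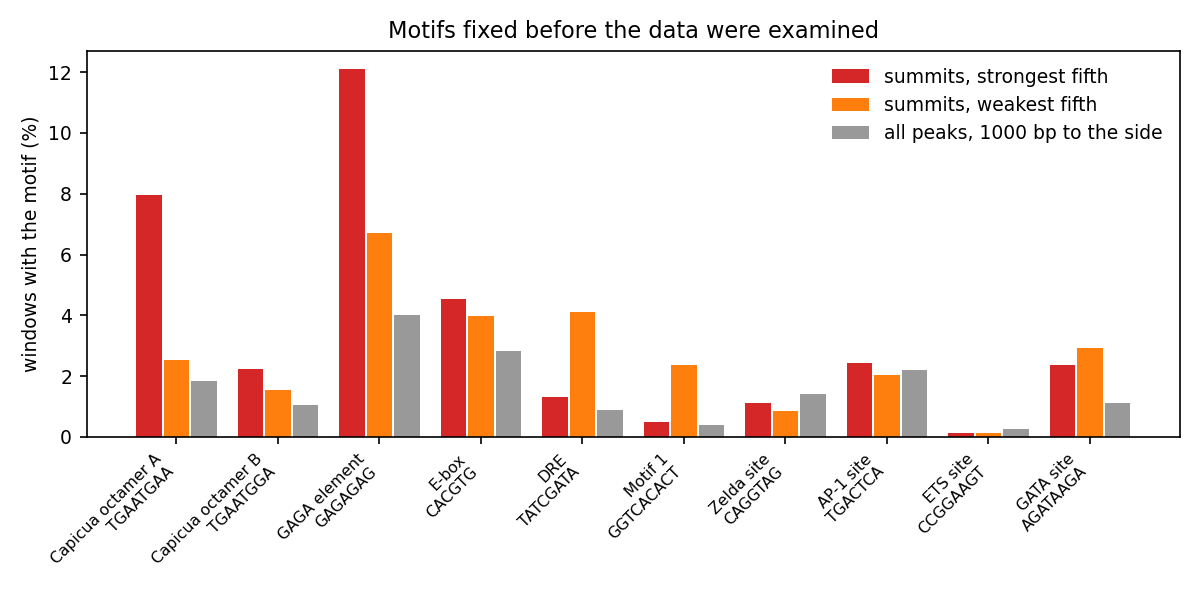
Percent of windows of 100 bp on each side of the summit that hold each motif, for the strongest and weakest 20% of peaks and for flanks 1000 bp to the side of all peaks. TGAATGAA is at 7.97% of the strongest and 2.52% of the weakest peaks, and the DRE at 1.33% and 4.13%.

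The list of known Capicua targets held 11 protein-coding genes, some of them described in embryos or imaginal discs. Of these 11 genes, 2 had a promoter peak (18.2%, 95% exact interval 2.28 to 51.8), against 30.5% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 0.568). These were pnt, an ETS factor downstream of EGFR, with a strongest promoter peak of 939 (471 ± 71.8, SD, n = 2), and Ets21C, another ETS factor, with 612 (308 ± 36.1, SD, n = 2). Without replicate 3, 4 of the 11 had a promoter peak. For aos, which encodes the EGFR inhibitor Argos, the summit nearest to a start was 2769 bp away, with a score of 139 and an octamer within 100 bp. The body of aos held 2 summits, the higher with a score of 258 and within 5000 bp of a start. For the microRNA gene mir-ban the nearest summit was 3851 bp away, with a score of 254 and no octamer. The nearest summits of the other genes on the list lay farther off: 14507 bp for CycE, 16656 bp for stg, 21955 bp for tll, 32322 bp for hkb, 35478 bp for ind, 49391 bp for pip, 51725 bp for mirr and 109686 bp for zen.

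The pnt gene, on 3R from 23290231 to 23346167, held 11 summits, the highest an intronic peak of 973. Its sequence holds 31 octamers of either form, a count made after its values were seen. Of these, 9 lay within 100 bp of a summit, while windows of that size around summits cover 3.78% of the gene. The intronic peak of 973 had 3 copies of TGAATGAA, at 23334512, 23334615 and 23334636, and the promoter peak of 939 had a copy at 23314453 to 23314460 on the minus strand, in TCGTTTTATGAATGAATTCCATTT.

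**Figure D3:**
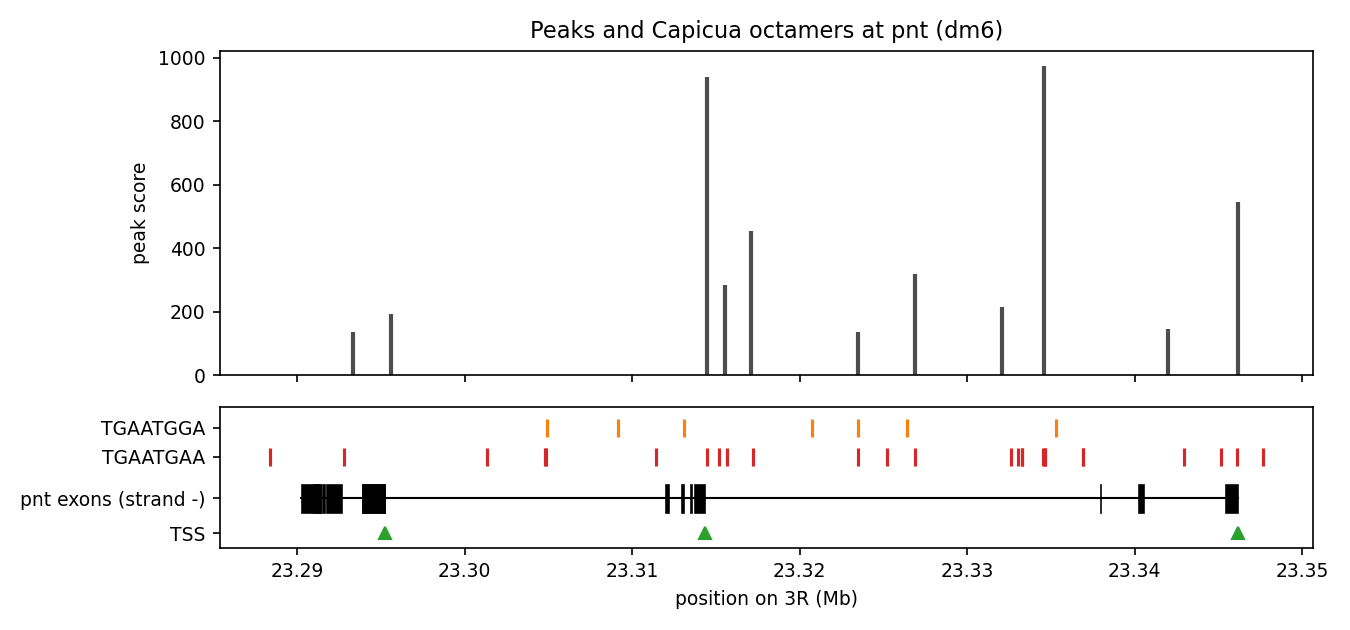
Map of pnt on 3R of dm6, with 5 kb on each side. Upper panel, score of each peak at its summit; lower panel, Capicua octamers, pnt exons and transcription start sites. The 11 summits in the gene include a peak of 973 in an intron and a peak of 939 at an internal promoter.

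Of 13945 protein-coding genes, 4257 (30.5%) had a summit within 1000 bp of a start, and 26 gene lists were set against this background. Genes of cytoplasmic ribosomal proteins, taken by a name pattern, were bound more often, 62 of 92 (67.4%, 95% exact interval 56.8 to 76.8, Fisher's exact test, adjusted p = 3.60e-12), with the highest scores at RpLP0-like (494, in the list by its name), RpS12 (488), RpS27 (471) and RpL7 (466). So were genes of Polycomb, Trithorax and insulator proteins, 18 of 24 (75.0%, 53.3 to 90.2, Fisher's exact test, adjusted p = 5.91e-05). The highest scores on that list were at mor (781), Trl (763), brm (468) and ph-d (361), and ash2 (1592) was not on it. Of 10 circadian clock genes, 8 were bound (80.0%, 44.4 to 97.5; Fisher's exact test, adjusted p = 0.00779), among them vri (1187), cry (601), Pdp1 (498) and Clk (468). Of 21 genes of insulin and TOR signalling, 12 were bound (57.1%, 34.0 to 78.2; Fisher's exact test, adjusted p = 0.0432), with high scores at Pdk1 (1627), REPTOR (1277), InR (1261) and Akt (1236). The insulin and TOR call was lost without replicate 1 (Fisher's exact test, adjusted p = 0.0888, with 0.0120 to 0.218 over the alternatives). It was also lost within 5000 bp of a start (0.136), with gene bodies (0.0757) and against genes with a relaxed promoter peak (0.218), by the same test. The circadian call was lost when only genes with a relaxed promoter peak were the background (Fisher's exact test, adjusted p = 0.142, with 0.000107 to 0.142 over the alternatives). A gene with several starts has more windows where a summit counts. The number of starts was not adjusted for in any of the 26 lists, whether bound more or less often. No background matched for transcription was used. Signal not specific to Capicua at strongly transcribed genes, such as those of ribosomal proteins, was therefore not separated from binding.

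Receptor tyrosine kinase genes narrowly missed the threshold, with 22 of 47 bound (46.8%, 32.1 to 61.9, Fisher's exact test, adjusted p = 0.0540). Their adjusted p was 0.00224 to 0.292 over the alternatives. By the same test they passed without replicate 3 (0.0120), among the stronger peaks of the list (0.0122) and with gene bodies (0.00224). They also passed with 1 summit per merged region (0.0497) and within 5000 bp of a start (0.0492). They did not pass without replicate 1 (0.0942), within 500 bp of a start (0.153) or against genes with a relaxed promoter peak (0.292). Genes of BMP signalling (9 of 15, with shn at 1566, sax at 659, brk at 270 and dally at 230) and gut markers (11 of 19, with GATAe at 457, Jon99Ci at 215, LManI at 183 and Mal-A1 at 161) each had an adjusted p of 0.0504 by Fisher's exact test. BMP genes passed without replicate 1 (0.0148) and without replicate 3 (0.00418), with 0.00418 to 0.290 over the alternatives, and 11 of the 15 were bound without replicate 3. They also passed among the stronger peaks of the list (0.0190), with gene bodies (0.00499) and with 1 summit per merged region (0.04997). They did not pass within 500 bp (0.170) or 5000 bp (0.0706) of a start or against genes with a relaxed promoter peak (0.290). Gut markers fell to 8 of 19 without either replicate (odds ratio 1.75 without replicate 1 and 1.63 without replicate 3, against 3.08), with an adjusted p of 0.429 and 0.467 by Fisher's exact test and 0.0166 to 1.00 over the alternatives. The promoter of pnt (939) followed those of sty, Mkp3 and spi among the receptor tyrosine kinase genes.

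Lists of chemosensory receptors, body-axis patterning, testis, neuronal and histone genes were bound less often than other genes. Of 179 chemosensory receptor genes 7 had a promoter peak (3.91%, 1.59 to 7.89; Fisher's exact test, adjusted p = 4.03e-18), of 30 genes of body-axis and segment patterning 1 (3.33%, 0.0844 to 17.2; Fisher's exact test, adjusted p = 0.00238), and of 22 testis genes 1 (4.55%, 0.115 to 22.8; Fisher's exact test, adjusted p = 0.0181). Without replicate 1, 2 of the 30 patterning genes were bound (6.67%, odds ratio 0.206 against 0.115). Among the stronger 50% of peaks the patterning call was lost (Fisher's exact test, adjusted p = 0.155; 2.19e-06 to 0.155 over the alternatives), and so was the testis call (Fisher's exact test, adjusted p = 0.369; 0.00216 to 0.506). With only genes that have a relaxed promoter peak as background, the testis call (Fisher's exact test, adjusted p = 0.506) and the chemosensory call (Fisher's exact test, adjusted p = 0.0999, with 2.24e-20 to 0.0999 over the alternatives) were lost. With that background 7 of 29 chemosensory genes were bound (24.1% against 45.6% of other genes), an odds ratio of 0.397 against 0.0973 over all protein-coding genes. The bound gene was hry in the patterning list and topi in the testis list, both named after their values were seen. Of 24 neuronal genes 2 were bound (8.33%, Fisher's exact test, adjusted p = 0.0432). The neuronal call was lost without replicate 1, when 4 of 24 were bound (16.7%, odds ratio 0.517 against 0.252, Fisher's exact test, adjusted p = 0.302). It was also lost among the stronger 50% of peaks, with 1 summit per merged region, within 500 bp of a start and with gene bodies. The other alternatives kept it (Fisher's exact test, adjusted p 0.0205 to 0.562 over all alternatives). None of 111 replication-dependent histone genes had a promoter peak (upper exact bound 3.27%; Fisher's exact test, adjusted p = 4.37e-17), but these genes stand in a repeated cluster where reads cannot be placed uniquely.

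The other lists did not pass, with adjusted p from 0.124 to 0.715 by Fisher's exact test. Of these, Hippo genes passed without replicate 3, with 11 of 17 bound (0.0148; 0.0148 to 0.407 over the alternatives). Without replicate 3, 5 of 20 Notch genes (odds ratio 0.783 against 0.455) and 3 of 10 JAK/STAT genes (1.03 against 1.58) were bound, and neither list passed. Among the stronger 50% of peaks, glial genes passed (0.0408; 0.0408 to 0.573), and proteasome genes passed as bound less often (0.0462; 0.0462 to 0.911). Muscle genes passed as bound less often within 5000 bp of a start (0.0497; 0.0497 to 1.00). Among pathways, Hippo had 9 of 17 genes bound (Diap1 668, hpo 278, crb 208, sd 206), Wnt 8 of 23 (Axn 340, nkd 257, sgg 241, pan 222), JAK/STAT 4 of 10 (Socs36E 402, Stat92E 264, dome 210, Socs44A 132) and Notch 3 of 20 (neur 199, kuz 198, mam 183). Among tissue markers, glia had 5 of 10 (Gs2 1054, Eaat1 955, moody 440, Indy 257), fat body and yolk 8 of 15 (Lpin 837, apolpp 264, Lsd-1 234, FASN1 190), immune response 12 of 26 (dl 793, Rel 653, Dif 473, imd 442), muscle 4 of 23 (Mef2 498, Zasp52 268, Tm1 185, Strn-Mlck 117), photoreceptors 4 of 20 (Rh5 647, rdgB 192, Gbeta76C 162, rdgC 152) and ovary 6 of 26 (Cp16 247, egl 242, Cp18 234, nanos 189). Cell-cycle genes had 6 of 28 (E2f1 516, Dp 367, dup 252, fzy 153), the proteasome 10 of 48 (Rpn8 388, Rpn13 313, Rpn5 175, Rpn2 173) and the mitochondrial respiratory chain 26 of 80 (COX7AL2 564, ND-51 287, ND-ASHI 263, ATPsynC 233).

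**Figure D4:**
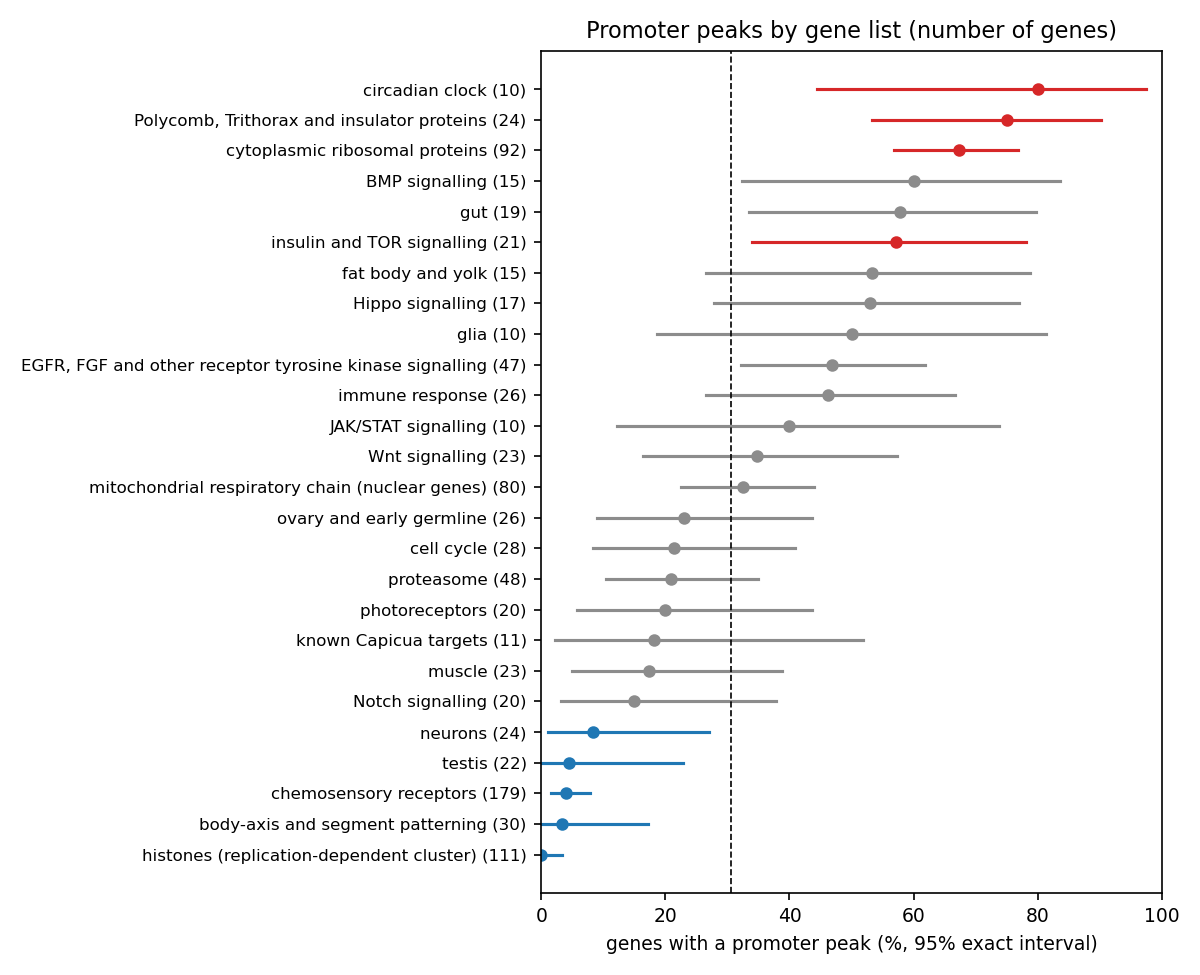
Percent of the genes of each list with a promoter peak, with 95% exact intervals and the number of genes in brackets; red and blue mark lists above and below other genes at an adjusted p under 0.05, and the dashed line is the share of all protein-coding genes (30.5%). Circadian clock genes are highest at 80.0%, and chemosensory receptors are at 3.91%.

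Promoters held most of the summits. Within 1000 bp of a protein-coding start lay 4626 of 7152 summits (64.7%, 95% exact interval 63.6 to 65.8), against a mean of 20.4% and a maximum of 21.9% in 1000 sets of random positions (permutation test, one-sided, p = 0.001, the smallest that 1000 sets can give). Of all summits, introns held 26.7% against 36.3% of random positions, intergenic sequence 6.17% against 28.4%, 3' UTRs 1.54% against 3.74% and coding exons 0.531% against 10.7% (permutation test, two-sided, adjusted p = 0.0024 for each), and the 5' UTR share did not pass (0.419% against 0.455%, permutation test, two-sided, adjusted p = 0.755). Each position counts in 1 class with promoters first, so the promoter share lowers the others by construction, and the shares outside promoters, an alternative chosen after seeing the data, differ. Of the 2526 summits outside promoters, introns held 75.5% (95% exact interval 73.8 to 77.2) against 45.5% of random positions outside promoters, and 5' UTRs 1.19% (0.803 to 1.69) against 0.572%. Intergenic sequence, with 17.5% against 35.7%, and coding exons, with 1.504% (1.07 to 2.06) against 13.5%, stayed below random (permutation test, two-sided, adjusted p = 0.0025 for each of these 4 classes). The 3' UTR share did not pass there (4.35% against 4.71%, permutation test, two-sided, adjusted p = 0.222). Of relaxed peaks outside the reproducible list, 43.2% were at promoters.

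Peaks were fewer on the X and on chromosome 4 than their lengths predict. The X held 893 peaks, 0.711 times the number expected (exact binomial test, adjusted p = 3.21e-31), and chromosome 4 held 23, 0.323 times (exact binomial test, adjusted p = 1.10e-10). On 2R there were 1582 peaks, 1.17 times the expected number (exact binomial test, adjusted p = 3.52e-11), and on 3R 1821, 1.06 times (exact binomial test, adjusted p = 0.00546), a call that was lost against the shares of relaxed peaks (exact binomial test, adjusted p = 0.421; 0.000396 to 0.421 over the alternatives). The ratio was 1.03 on 2L (exact binomial test, adjusted p = 0.250) and 1.02 on 3L (exact binomial test, adjusted p = 0.296).

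Non-coding genes had a promoter peak less often than protein-coding genes in 4 of 5 classes. The shares were 64 of 290 tRNA genes (22.1%; Fisher's exact test, adjusted p = 0.00316), 61 of 269 snoRNA genes (22.7%; Fisher's exact test, adjusted p = 0.00614), 246 of 1944 lncRNA genes (12.7%; Fisher's exact test, adjusted p = 4.42e-68) and 33 of 260 miRNA genes (12.7%; Fisher's exact test, adjusted p = 7.65e-11). For snRNA genes, 7 of 32 (21.9%), the difference did not pass (Fisher's exact test, adjusted p = 0.341), and the snoRNA call was lost among the stronger 50% of peaks (Fisher's exact test, adjusted p = 0.349, with 0.000662 to 0.349 over the alternatives). A gene with several starts has more windows in which a summit counts, and the number of starts was not adjusted for. Whether reads can be placed uniquely at these non-coding genes was not examined.

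Scores of the 2 replicates were correlated over the whole reproducible list. Across the 7122 peaks with a match in both, Spearman's rho between their scores was 0.728 and Pearson's r of log2 scores 0.800; these describe peaks, which are not independent replicates. The rank correlation was 0.697 in the strongest 20% (n = 1429, Pearson's r of log2 scores 0.786) and -0.101 in the weakest 20% (n = 1426, Pearson's r 0.477). Selection on the pooled score narrows the range in the weakest 20%, which may push the rank measure down, and summits of an interval often share a replicate score. Why the 2 measures differ there was not tested. The median log2 ratio of replicate 1 to replicate 3 was -0.09 (SD 0.51), and 360 peaks (5.05%) were over 2 times apart once this was removed. A relaxed peak overlapped 99.8% of the 7152 peaks in replicate 1 and 99.7% in replicate 3. The list is the top of the pooled scores of these same replicates, so these shares, and the 16.1% at random positions, are no independent measure of their agreement. Among the strongest 7152 peaks of each replicate the shares were 89.7% (95% exact interval 88.95 to 90.38) and 90.3% (89.5 to 90.9).

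**Figure D5:**
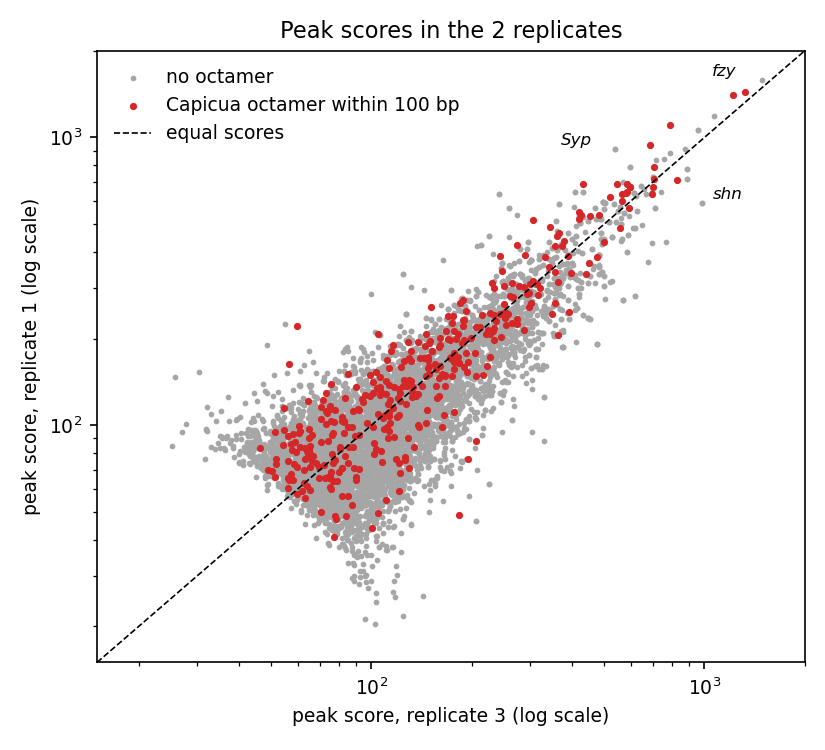
Scores of matched peaks in replicate 1 against replicate 3, both on log axes; each point is a peak of the reproducible list, red where a Capicua octamer lies within 100 bp of the summit, and the dashed line marks equal scores. Spearman's rho is 0.728, and the labelled peaks are those nearest to fzy, shn and Syp.

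The authors' reproducible list on the older dm3 genome held 7372 peaks, and that on dm6 7152. In these lists the X held 12.98% of peaks in dm3 and 12.49% in dm6, and 3R 25.4% and 25.5%. In the relaxed lists the X shares lay farther apart between builds: 19.1% in dm3 and 15.7% in dm6 for the pooled list, 18.1% and 15.4% for replicate 1, and 19.4% and 16.3% for replicate 3.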

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

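The tests in this part were fixed before their values were seen, but after the patterns themselves were noticed. On the dm3 build, 9 peaks of the authors' reproducible list lie on the unplaced sequence Uextra, which the dm6 lists do not hold; they enter the dm3 peak count, the total behind the dm3 shares per arm and the dm3 alternatives for the replicates. The strongest 2 of all 7372 dm3 peaks are among them, with scores of 7607 and 4761. In replicate 3 these scored 7553 and 4626, and in replicate 1 they scored 53.8 and 41.1, a ratio of 140 and 113. All 9 have a peak in replicate 3 and 5 have a peak in replicate 1. What this sequence is was not tested, since a dm3 genome was not used here.

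Most peaks, 94.8%, had neither Capicua octamer sought here (TGAATGAA or TGAATGGA) within 100 bp of the summit. Summits that lie beside the octamer would need an excess over flanks of at least 40 percentage points at 300 bp, and it was 3.85 (95% interval 2.89 to 4.80); octamers with 1 mismatch in its place would need at least 20, and the excess was -0.797 (-2.34 to 0.749), so the tables argue against both as the cause of most peaks. Signal at promoters of broadly active genes remains a candidate explanation for part of the peaks: the DRE or Motif 1 was 3.04 points (1.67 to 4.41) more frequent where no octamer stood. That covers little of the pattern, since these elements were at 4.65% of peaks without an octamer and at 1.60% of peaks with one. Octamers also went with strong peaks and these elements with weak ones. Peaks without an octamer lay at promoters more often (65.0% against 59.1%). The difference was adjusted for neither, so it cannot decide for this explanation. No biological explanation was tested, and recruitment by other proteins stays open.

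The X held fewer peaks than expected, at 0.734 of its share of protein-coding starts. A lower copy number of the X in pooled males and females was not excluded: with X scores raised by 4/3, for equal numbers of each sex, and as many peaks taken, the ratio was 1.08 (95% interval 1.02 to 1.13). The sex ratio is not in the labels, and how the control entered the scores is not given in the sources used here. Raising X scores must raise the X share whatever lowered it, so the value shows only that a factor of this size is enough (at least 0.95 was needed) and is no evidence for copy number over other causes. The cause stays open, and no biological explanation was tested.

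The tagged gene, cic, holds 2 of the 25 strongest peaks. Extra copies of the cic region in the tagged line may raise signal over the whole region, and binding of Capicua at its own gene would raise single sites. Within 20 kb of its starts lay 29 relaxed summits, against a median of 14 around protein-coding genes, which is at the 95.1 percentile, between the bounds of 90 and 99 set for a decision. These explanations cannot be told apart here, because peak lists hold no coverage between the peaks.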

How the results depend on the processing

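The alternatives with 1 summit per merged region, and those for annotation classes (among them shares outside promoters), motifs and the ranking of octamers, were chosen after seeing the data. Of 141 alternative values for the main results, 116 kept their direction and their side of the threshold, kept their value within its spread or, for counts and ranks, moved too little to be called changed. The promoter share, the octamer excess at summits, its relation to strength and the deficits on the X and chromosome 4 kept their direction and their side of the threshold under every alternative run. The 141 leave out 247 values for single gene lists and motifs. Of those 247, 195 kept their label, 20 became stronger, 20 became weaker and 12 changed direction. Taking the top of the pooled relaxed list instead of the reproducible list gives the identical peaks and tests nothing, and arm tests on dm3 were not run. Other octamers of the same base composition as TGAATGAA number 420 with it, and 3 including it reached its excess, the others being ATCTTATC and TCTTATCA.

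Replicate agreement fell to a rho of 0.625 with summits within 100 bp and 0.657 over all shared relaxed peaks. The share of peaks found in replicates 1 and 3 was 79.4% and 81.0% with a reciprocal overlap of 50%, 95.8% and 95.9% with summits within 100 bp, and 89.7% and 90.3% among as many peaks as the reproducible list holds; in the last, fewer replicate peaks enter by construction. TGAATGAA ranked 4 in the strongest 20% of peaks, and between 23 and 68 without either replicate.

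Among the stronger 50% of peaks the 5' UTR share was 0.475%, now above random without passing (permutation test, two-sided, p = 0.893). In the same peaks 2L had 1.09 times the expected peaks and passed, and the odds ratio of snoRNA genes was 0.827 and no longer passed. Outside promoters, introns held 75.5% and 5' UTRs 1.19% of summits, both now above random, and 3' UTRs held 4.35% and no longer passed; the promoter share fixes part of the shares over all summits by construction. Against protein-coding starts, 3L was at 1.11 and passed and 2L at 0.965; against relaxed peaks, 3R was at 1.02 and no longer passed. The cause of the other changes was not tested.

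Lists bound more often numbered 4 and lists bound less often 5. The first count was between 4 and 7 without either replicate, 7 among the stronger 50% of peaks (with 3 bound less often) and 7 with 1 summit per merged region. With only genes that have a relaxed promoter peak as background it was 2, with 2 bound less often, where fewer genes enter by construction. Lists that did not pass changed direction, without passing, as follows. Among the stronger 50% of peaks the odds ratios were 1.35 for known Capicua targets, 1.03 for Notch, 1.03 for ovary and 0.446 for the respiratory chain. The ratio of known Capicua targets was between 0.621 and 1.32 without either replicate. With a distance of 500 bp the respiratory chain was at 1.00, and with 5000 bp JAK/STAT was at 0.674 and the proteasome at 1.61. With gene bodies photoreceptors were at 1.14, and among genes with a relaxed peak Wnt was at 0.883, JAK/STAT at 0.978 and the respiratory chain at 0.867. Unknown depth limits which weak peaks each replicate could show.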

Other observations

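The genes described in this part were chosen after their values were seen. Several long genes held many summits of the reproducible list in their body or promoters: Pdp1, a clock gene, held 26 over 55912 bp, and SNF4Agamma, a subunit of AMP-activated kinase, bun and shn held 23 each over 73531, 91072 and 58309 bp. InR, the insulin receptor, held 19 over 49074 bp. The ecdysone-response genes Eip74EF and Eip75B held 18 and 17, with promoter peaks of 218 and 273 and stronger peaks of 629 and 576 elsewhere in the gene, and tara held 17 over 34679 bp.

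Some peaks of the reproducible list differed widely between replicates. After the median ratio was removed, replicate 1 exceeded replicate 3 most at smg (147 against 25.7, log2 ratio 2.61), Dpit47 (153 against 30.3, 2.43) and Dll (224 against 55.0, 2.11). Replicate 3 exceeded replicate 1 most at fwd (124 against 21.7, log2 ratio -2.43), egh (143 against 25.6, -2.40) and atos (103 against 20.4, -2.24). Peaks with an octamer had a median score of 228 and lay at promoters in 59.1% of cases (95% exact interval 53.9 to 64.1), and peaks without had a median of 178 and lay at promoters in 65.0% (63.8 to 66.1).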
